A study of Mus musculus with 6 samples.

How the data were processed

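Total RNA from mouse pancreatic islets was extracted with Trizol and RNeasy columns, amplified and biotin-labelled with an Ambion MessageAmp kit and hybridised to Illumina mouse bead arrays, per the labels' protocols. The 6 arrays cover 2 treatments (control IgG or the serpin B13 antibody B29) in 3 classes of islet diameter, with 1 array per treatment and class. The deposited raw table holds 46255 rows (45281 probes and 974 control rows) with an intensity and a detection p-value per array. The deposited intensity values were neither background-corrected nor normalized between arrays, as their values show, and the deposited detection p-value came in 936 equal steps. The authors' value table holds log2 values, with limma 3.34.9 named per the submitters' processing notes; that they were background-corrected and quantile-normalized was read from the values, since the arrays share their quartiles and extremes. Of the raw table's rows, 22 had a word of a gene description in place of a signal and were not used; 2 of these were detected.

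The raw intensities were normalized again with limma 3.58.1 in R 4.3.3: the neqc function took the background from the detection p-values, added an offset of 16 and applied quantile normalization. The result differed from the authors' log2 values by at most 0.00037. Each array's column had a median of 4.29 in the authors' table. A probe was tested where its detection p was under 0.05 on at least 2 of 6 arrays, which left 16774 probes. Gene names came from the probe table given for the platform and from a RefSeq gene table of assembly GRCm38.p6, used for names only: 35784 probes matched 1 symbol (28620 by Entrez gene, 2637 by transcript and 4527 by the file's own symbol) and 9497 matched none. Where a value per gene was needed, the probe with the highest mean was taken. Names of the platform such as Igk-C, Igh-6 and Iap were kept as given. Probes without a name numbered 2282 of those tested and are not named in the text. No genome positions were used.

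Treatment over sizes and the size comparisons came from 1 limma fit (lmFit and eBayes) with treatment and diameter class as additive factors, which left 2 residual degrees of freedom per probe (6.60 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The residual spread of this fit holds the differences of the treatment effect between classes as well as noise. Within a class there was 1 array against 1, so probes at least 2-fold apart and detected on either array were counted without a test. These counts used the normalized values as they stood, also where 1 array was not detected. For the fold of a named gene, a value not detected was put at the detection floor, the lowest level of a detected probe on that array. Such a fold is given as at least that. Gene lists were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, on 26 of the 30 lists that had at least 3 tested genes. The lists of T cell, B cell, Schwann cell and adipocyte markers had 1 tested gene each and were not tested. In a class, a list's median was placed among 10000 random lists of the same size and like brightness. Percentages, counts and correlations across genes describe these arrays.

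The design, the tests, the 30 gene lists, the rule for the genes named and most alternatives were chosen before the data were examined. The rule took, for treatment over sizes, the 10 highest and 10 lowest mean log2 ratios with the same sign in all classes, those past the threshold first; for each class the 5 highest and 5 lowest ratios; for size the 10 highest and 10 lowest past the threshold with the same sign in both treatments; 20 genes of the study's subject; and up to 4 members of each list. Any gene outside that rule was named after its values were seen, as were 4 further lists, of lymphoid, core macrophage, STAT5 target and endocrine progenitor genes. Alternatives were other scalings (cyclic loess, median centring), other background corrections (none, or normexp with an offset of 50), the authors' values, other filters, 1 probe per gene, a trended and robust eBayes, the other factor left out, the acinar list left out, and each array or pair left out. Further alternatives added after the data were seen were to leave out 112 probes at least 2-fold brighter in small than in large IgG islets, and to count size differences in each treatment alone.

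The fits were tested on simulated data with 16774 probes, with 50 probes changed at each fold size. The treatment test recovered 52% of 1.5-fold changes and 100% of 2-fold, 4-fold and 8-fold changes, with 10.2% of its calls false. The comparison of over 200 with under 100 µm recovered 56%, 98%, 100% and 100%, with 11.9% false, and that of 100 to 200 with under 100 µm recovered 34%, 100%, 100% and 100%, with 7.22% false. The simulated treatment changes were the same in all 3 classes. With 200 changed probes the adjusted threshold is easier to reach than in the data, where 1 probe passed for treatment. These shares therefore do not show that real 2-fold changes would have passed. A list of 15 genes shifted 1.5-fold among 26 passed camera at the preset correlation (adjusted p = 9.1e-20) and was missed with an estimated correlation (adjusted p = 0.251), with 0 false lists in either. The simulated genes varied independently, so the 0 false lists do not test the preset correlation on lists whose genes vary together. Estimated correlations of the real lists ran from -0.43 (clade B serpins) to 0.87 (Reg family). Figures were drawn with matplotlib 3.10.9.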

Results

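Pancreatic islets of BALB/c mice were profiled on Illumina mouse bead arrays after injection of a control IgG antibody or of B29, a monoclonal antibody against serpin B13, a clade B serpin that inhibits cysteine proteases such as cathepsin L. The mice received 4 intraperitoneal injections of 25 µg (100 µg in all) from 2 weeks of age, and the islets were taken at 5 weeks of age, 2 weeks after the last injection. Islets were separated by diameter into 3 classes (under 100, 100 to 200 and over 200 µm), and each class of each treatment went onto 1 array, which gave 6 groups of 1 array. Between 14800 (32.7%) and 15914 (35.2%) of the 45281 probes were detected per array, and median raw intensities of 73.7 to 76.6 stood close to the medians of 71.3 to 73.9 of the control probes. The comparisons used 16774 probes, of which 14492 stood for 10530 named genes. The number of arrays limits the precision: a single class had no replicate, and the labels do not say whether the 3 classes of a treatment came from the same mice, so that the tests below measure agreement between classes and not between mice.

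The first question was whether the genes at the centre of the study differed between the antibodies. The Serpinb13 transcript was not detected on any of the 6 arrays: its raw intensity ran from 67.2 to 72.5, with detection p-values from 0.556 to 0.975. The injected antibody acts on the protein, so this probe does not check the treatment. Ctsl, which encodes cathepsin L, had a mean log2 ratio of B29 to IgG over the 3 classes of -0.13 (SE 0.14), Cdh1, the gene of E-cadherin, of -0.00 (SE 0.13) and Ctnnb1, the gene of its partner beta-catenin, of -0.03 (SE 0.16). The hormone genes Ins2 (-0.08), Gcg (-0.08) and Sst (-0.10) had ratios as small, with Ins2 at the top of the intensity range, where differences are compressed. Notch1 stood at 0.20, the beta cell transcription factors Pdx1 and Mafa at 0.23 and -0.22, and the proliferation marker Mki67 at 0.29. None of these genes passed limma's test over all genes (adjusted p from 0.966 to 0.999). The Reg3g probe was not detected, and Ins1 had no named probe.

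The next comparison asked which genes differed between B29 and IgG in the same direction across islet sizes. Cish, a cytokine-induced suppressor of cytokine signalling, was the 1 gene that passed: it fell 2.91-fold with B29 (log2 ratio -1.54, SE 0.14, adjusted p = 0.0485), and was 2.72-fold dimmer in islets under 100 µm, 3.53-fold in those of 100 to 200 µm and 2.56-fold in those over 200 µm. Other genes were dimmer with B29 in all 3 classes without passing. They include the activity-regulated transcription factor Npas4 (-1.02, SE 0.20), the EGF receptor inhibitor Errfi1 (-0.94, SE 0.19), the transcriptional coregulator Cited2 (-0.90, SE 0.13), Rpf1 (-0.80), Sin3a (-0.71), Folr1 (-0.67), Dmac2l (-0.66), the islet hormone gene Ppy (-0.65) and Zfand2a (-0.64). Brighter in all 3 classes without passing were Thada (0.75, SE 0.15), Mkln1 (0.73), Atp5mpl (0.70), Ppcs (0.70), Gm10060 (0.70), Zfp445 (0.70), the neuropeptide gene Cartpt (0.68), Trim41 (0.68) and H2-Ea (0.66). Reg2, a secreted lectin of the regenerating islet-derived family, had the highest fitted mean (2.19, SE 0.52), but lay below background over 200 µm with both antibodies. Neurog3, the transcription factor of endocrine progenitors, was also brighter in each class (0.47, 1.07 and 0.36; mean 0.63, SE 0.17). Adjusted p was 0.686 for Cited2 and 0.966 for the others, and 783 probes (4.67%) had an unadjusted p under 0.05. The other probes of Cited2 (-0.29 and -0.11), Folr1 (-0.23), Cartpt (0.32), Mkln1, Rpf1 and Sin3a did not share the size of the difference.

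The Cish call was lost with cyclic loess scaling, without background correction, with another background method, and without the pair of arrays under 100 µm or of 100 to 200 µm: over its 8 alternatives the log2 ratio stayed between -1.63 and -1.12, and the adjusted p ran from 0.00102 to 0.992. No probe passed either with 1 probe per gene, without the filter on dim probes or without the size factor, which are not among these 8. Without the pair over 200 µm, 3 genes passed: Cish (-1.63, adjusted p = 0.00102), Reg2 (3.19, adjusted p = 2.17e-06, with 1 of its 4 values below background) and Acta2 (1.22, adjusted p = 0.0262), the smooth muscle actin gene, whose 3 other probes had ratios of 0.16, -0.34 and 0.27 under 100 µm against 1.40.

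**Figure D1:**
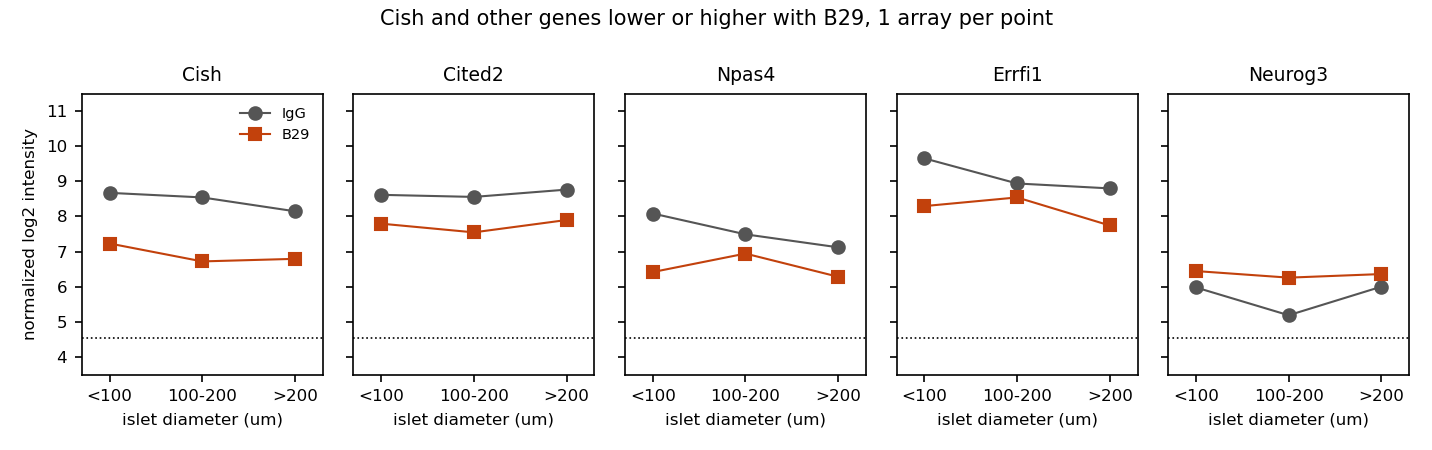
Normalized log2 intensity of Cish, Cited2, Npas4, Errfi1 and Neurog3 on each array, against islet diameter in µm, with IgG in grey circles and B29 in orange squares. Each point is 1 array. The dotted line is the lowest level of a detected probe, on the array where that level was highest (4.54). B29 lay below IgG for Cish by -1.44, -1.82 and -1.35, and Neurog3 lay above it by 0.47, 1.07 and 0.36.

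Gene lists fixed in advance were then compared between the antibodies over the 3 classes. With B29 the heat shock list, made of stress-induced chaperones, fell (camera, adjusted p = 0.000187; adjusted p = 0.732 with an estimated correlation): 4 of 7 genes were lower in all 3 classes, among them Hspb1 (-0.59) and Dnajb1 (-0.52), and 3 genes passed adjusted over the list alone, though 0 passed over all genes. Immediate early genes, which are switched on within minutes of a stimulus, fell as a list (11 genes, adjusted p = 0.00950; adjusted p = 0.732 with an estimated correlation), with medians of -0.46, -0.15 and 0.01 from the smallest to the largest class. Atf3 (-1.13) and Junb (-1.04) were far lower under 100 µm, while Ier2 was higher in every class (mean 0.39). The hypoxia and glycolysis list (14 genes) also fell (median ratios -0.12, -0.11 and -0.07, adjusted p = 0.0385; adjusted p = 0.732 with an estimated correlation). None of its genes passed, even adjusted over the list alone; 5 were lower and 1 higher in all 3 classes, with Tpi1 (-0.46) and Aldoa (-0.38) lower and Pgk1 (0.23) higher. The hypoxia call was also lost without background correction and without any 1 of the 3 pairs of arrays.

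The Reg family rose as a list with B29 (5 genes, adjusted p = 0.00109), as did the Notch pathway list (9 genes, adjusted p = 0.00950; Neurog3, which Notch signalling represses, 0.63, the target gene Nrarp 0.37, Jag2 0.02, Hey1 -0.05), the fibroblast and matrix list (13 genes, adjusted p = 0.0426; Acta2 0.72, Dcn 0.25) and the macrophage list (10 genes, adjusted p = 0.0426; Lyz1 0.77, H2-Ab1 0.37). Each of these 4 calls was lost with a correlation estimated from the data (adjusted p = 0.732 with an estimated correlation). Reg1, the only gene of the Reg list detected over 200 µm, stood at -4.00 there, so that the Reg list did not share 1 direction. The acinar list, made of digestive enzymes and their regulators, fell (32 genes, adjusted p = 0.000522; adjusted p = 0.732 with an estimated correlation), but its direction was not shared: its median ratio was 0.29, 0.48 and -3.04 from the smallest to the largest class. With fry, 0 lists passed. Adjusted over the list alone, 4 Reg genes, which lay below background over 200 µm, and 0 acinar, Notch, fibroblast or macrophage genes passed. The fibroblast and macrophage calls were lost with cyclic loess and with either other background method, the Reg and acinar calls without background correction. Without the pair over 200 µm the acinar median became 0.33. Without that of 100 to 200 µm the macrophage median became -0.05 and the Notch and fibroblast calls were lost. Only the acinar and macrophage calls held without the pair under 100 µm.

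The 18 other lists did not pass (adjusted p from 0.0700 to 0.974). Of the 18 beta cell identity genes, 7 were lower with B29 in all 3 classes and none was higher in all 3 (median ratios -0.20, -0.13 and -0.02, adjusted p = 0.0700); Ucn3 (-0.36) and G6pc2 (-0.23) had the lowest means, Pdx1 (0.23) and Slc30a8 (0.18) the highest. The beta cell list passed with median centring (adjusted p = 0.0251) and without the pair over 200 µm (adjusted p = 0.0345); over all 3 pairs it had an adjusted p = 0.732 with an estimated correlation. The delta and PP cell list had a low median ratio under 100 µm (-0.35, percentile 0.72), against -0.14 and 0.05 in the larger classes. Over the 3 classes, alpha cell genes (4 genes, adjusted p = 0.559) and delta and PP cell genes (7 genes, adjusted p = 0.467) did not pass as lists. Nor did the 21 proliferation genes (median ratios 0.08, 0.04 and -0.11, adjusted p = 0.908) or the 12 cell cycle regulators (adjusted p = 0.871), with Cdkn1a at -0.38 and Ccnd3 at 0.30. Among 10 cathepsins and their inhibitors (adjusted p = 0.467), the cysteine protease gene Lgmn was higher in every class (0.44, 0.82 and 0.68) and passed adjusted over the list alone, but not over all genes (adjusted p = 0.966). The 12 adherens junction and Wnt genes (adjusted p = 0.467) and the 3 clade B serpins (adjusted p = 0.559) did not pass either.

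In islets under 100 µm, the Reg genes differed most between the antibodies. With B29, Reg2 was 13.0-fold brighter (log2 ratio 3.70), Reg3b 5.42-fold (2.44) and Reg3a 4.15-fold (2.05), while Reg3d stood at 1.04 and Reg1 at 0.61. The list's median ratio of 2.05 lay above those of all 10000 random lists of like size and brightness (percentile 100). Acta2 (1.40) and the bromodomain gene Brd3 (1.39) were also brighter, and Npas4 (-1.67), Zfc3h1 (-1.57), Cish (-1.44), the immediate early gene Csrnp1 (-1.44) and Errfi1 (-1.36) were dimmer. On the same arrays the acinar list had a median ratio of 0.29 (percentile 100), with 25 of 32 genes brighter, and heat shock (-0.50, percentile 0.0900) and immediate early genes (-0.46, percentile 0.0300) were dimmer. In all, 63 probes were at least 2-fold brighter and 33 at least 2-fold dimmer among 16111 detected on either array. No test is possible with 1 array against 1. Simulated noise with the residual spread of the additive fit put 18 of 16574 unchanged probes past 2-fold. That spread was not measured between replicate arrays, so this count does not measure what 2 arrays of the same treatment would give.

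**Figure D2:**
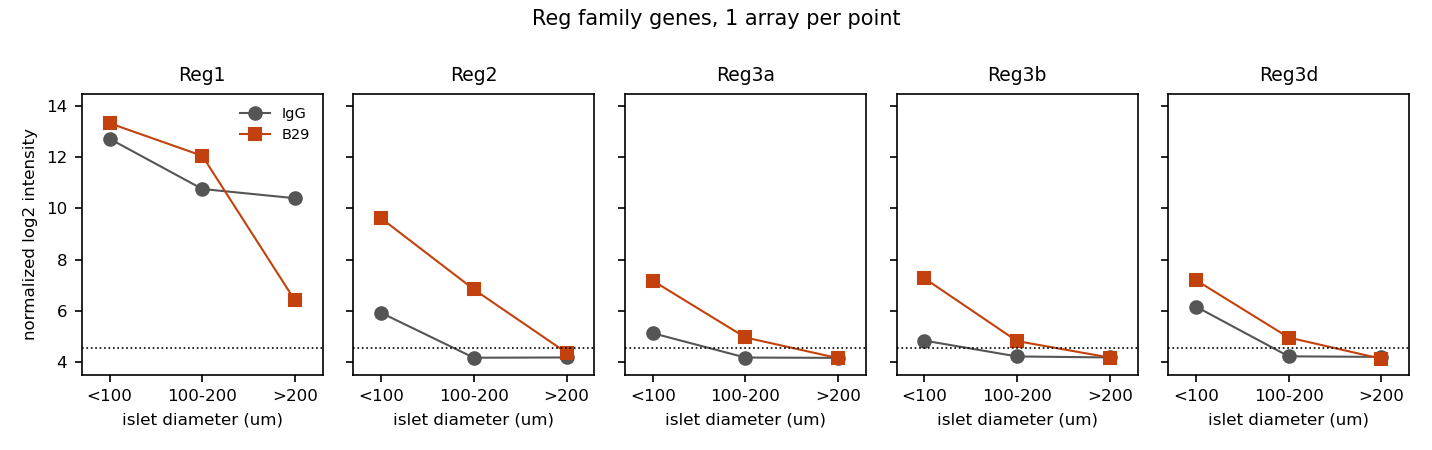
Normalized log2 intensity of the 5 Reg genes on each array, against islet diameter in µm, with IgG in grey circles and B29 in orange squares. Each point is 1 array. The dotted line is the lowest level of a detected probe, on the array where that level was highest (4.54). Under 100 µm Reg2 stood at 5.92 with IgG and 9.61 with B29, while over 200 µm Reg2, Reg3a, Reg3b and Reg3d lay at the background with both.

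In islets of 100 to 200 µm, genes of immune cells were brighter with B29. The immunoglobulin kappa gene Igk-C was 20.2-fold brighter (4.33), the leukocyte surface gene Cd52 stood at 2.35, Mfge8, a phagocytosis adaptor gene, at 2.15 and the lysozyme gene Lyz1 at 1.82. The macrophage list had a median ratio of 0.42 (percentile 100, 9 of 10 genes brighter), led by Lyz1, H2-Ab1 (1.31), Lyz2 (1.23) and Cd74 (1.07), of which the last and H2-Ab1 are antigen presentation genes that B cells also express. Reg2 was at least 5.08-fold brighter, since it was not detected with IgG, and Reg3a, Reg3b and Reg3d were at least 1.38-fold, 1.25-fold and 1.38-fold brighter; Reg1 stood at 1.30. The acinar list had a median of 0.48 on these arrays (percentile 100, 30 of 32 genes brighter). Cish (-1.82), the folate receptor gene Folr1 (-1.10), Arhgap44 (-1.08), Phlda1 (-1.07) and Ppy (-1.05) were the dimmest. In all, 67 probes were at least 2-fold brighter and 10 dimmer among 16221, without a test. The same simulated noise, with the same limit, put 33 of 16574 unchanged probes past 2-fold.

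**Figure D3:**
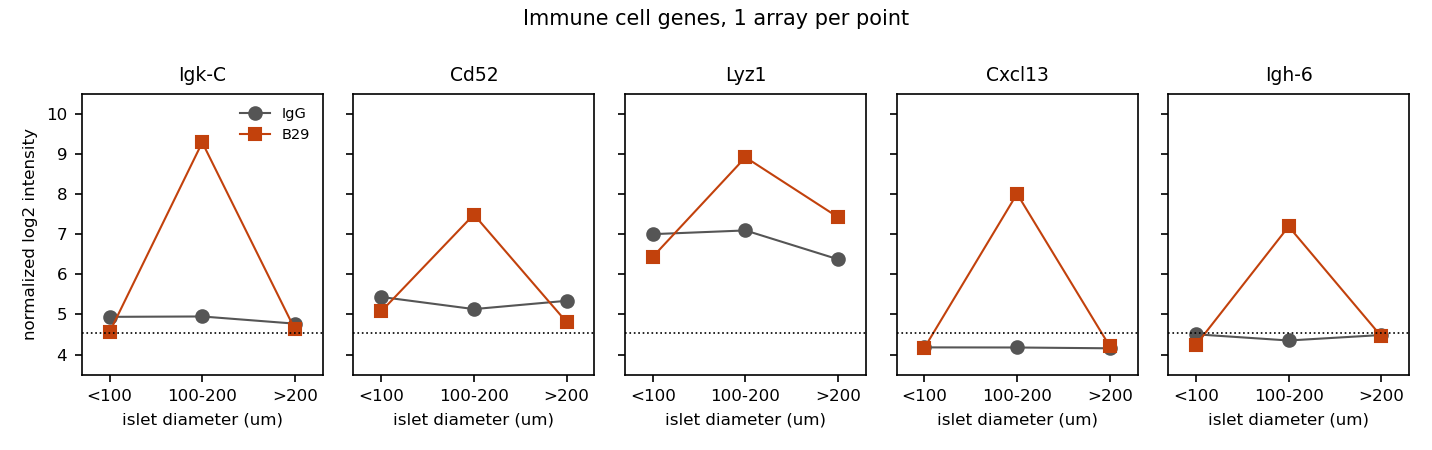
Normalized log2 intensity of 5 immune cell genes on each array, against islet diameter in µm, with IgG in grey circles and B29 in orange squares. Each point is 1 array. The dotted line is the lowest level of a detected probe, on the array where that level was highest (4.54). Cxcl13 stood at 8.0 on the B29 array of 100 to 200 µm, against a mean of 4.18 over the other arrays; Cxcl13 and Igh-6 were picked after their values were seen.

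In islets over 200 µm, genes of the exocrine pancreas were far dimmer with B29. Reg1, which acinar cells express, had a log2 ratio of -4.00, and the pancreatic enzyme and cofactor genes Cela3b (-3.83), Clps (-3.77), Pnliprp1 (-3.60) and Cpa1 (-3.57) followed. The acinar list had a median ratio of -3.04 (percentile 0.0), with 2 of 32 genes brighter. With 1 array per antibody, a different share of acinar tissue in the 2 samples cannot be told apart from an effect of B29. Mkln1 (1.67), Iap (1.23), Tefm (1.20), the thrombin receptor gene F2r (1.18) and Nceh1 (1.15) were the brightest with B29, while a second probe of Mkln1 stood at 0.03. The beta cell list (-0.02) and the immediate early list (0.01) had medians near 0. In all, 31 probes were at least 2-fold brighter and 114 dimmer among 15681, without a test. The simulated noise, with the limit given above, put 29 of 16574 unchanged probes past 2-fold. Of the 114 dimmer probes, 83 were left without the acinar list, and with median centring the split was 8 brighter and 158 dimmer.

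**Figure D4:**
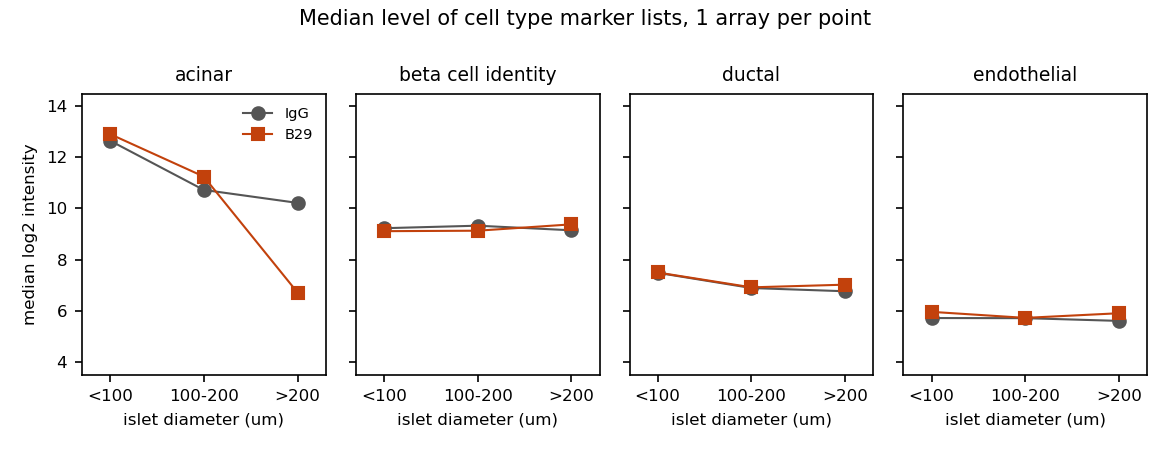
Median log2 intensity of 4 cell type marker lists on each array, against islet diameter in µm, with IgG in grey circles and B29 in orange squares; each point is the median of a list's genes on 1 array. The acinar median ran from 12.7 to 10.2 with IgG and from 12.9 to 6.71 with B29, while the beta cell median stayed between 9.11 and 9.38.

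How far the differences between B29 and IgG were shared between islet sizes was examined next. Across 16774 probes the log2 ratios of the classes were nearly unrelated: Pearson's r was 0.0610 between under 100 and 100 to 200 µm (Spearman's rho 0.0401), -0.00153 between under 100 and over 200 µm (0.0193) and -0.0795 between 100 to 200 and over 200 µm (-0.0374); genes are not independent replicates. At least 1.5-fold in the same direction in all 3 classes were 5 probes, of Cish, Cited2 and 3 without a gene name, against a mean of 5.33 for the patterns with 1 class turned. The pattern with the class over 200 µm turned held 13 probes. The share of probes with the same sign in all 3 classes was 25.5%, where unrelated signs give 25%. Reg2 went from 3.70 under 100 µm to a level below background over 200 µm, and Reg1 from 0.61 to -4.00; these differences between classes were not tested, since a fit with the interaction leaves no residual degrees of freedom.

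The separation by diameter allowed a comparison of large with small islets over both antibodies. The acinar list had a median level of 12.7 (IgG) and 12.9 (B29) under 100 µm, against 10.2 and 6.71 over 200 µm. For the genes and lists below, a different share of acinar tissue in the classes therefore cannot be told apart from a change within islet cells. From islets under 100 to those over 200 µm, acinar genes fell most: the secreted phospholipase gene Pla2g1b fell by 5.44 on the log2 scale (SE 0.78, adjusted p = 0.0282), the mucosal scavenger gene Dmbt1 by 5.43 (SE 0.52, adjusted p = 0.00559) and the zymogen granule gene Cuzd1 by at least 5.21 (adjusted p = 0.00559), as the B29 array over 200 µm did not detect it. The lipase gene Pnliprp2 (-5.27), the zymogen granule membrane gene Gp2 (-5.16), the kallikrein genes Klk1b27 (-5.14) and Klk1b26 (-4.98), the protease gene Ctrc (-5.12), the lipase gene Cel (-5.08) and the disulfide isomerase gene Pdia2 (-5.05) fell too, as did the ductal gene Muc1 (-1.90). The ductal list of 5 genes had a median of 0.15 and did not pass (camera, adjusted p = 0.548). The acinar transcription factor Ptf1a and Reg3d fell to below background over 200 µm, at least 5.05-fold and 4.43-fold. The ATP synthase gene Atp5b rose by 1.93 (SE 0.22, adjusted p = 0.0101) and Iapp, which encodes the amyloid peptide secreted with insulin, by 1.19 (SE 0.16, adjusted p = 0.0185). Among the other risers were Iap (2.07), the translation factor gene Eif3d (1.16), Snw1 (1.13), Chmp5 (1.12), Nab2 (1.07), Stab1 (1.05), the glycolytic gene Aldoa (1.00) and Fkbp1b (0.96); a second probe of Stab1 stood at -0.22. In all, 16 probes rose and 73 fell (1750, or 10.4%, at an unadjusted p under 0.05). From under 100 to 100 to 200 µm, 14 probes fell and 0 rose (1000 unadjusted), and 0 differed between 100 to 200 and over 200 µm in limma's test (810 unadjusted). The count of 89 was 0 without the B29 array under 100 µm, 5 without the IgG array under 100 µm and 224 without the IgG array over 200 µm. It was also 0 without background correction, with the other background method and without the filter on dim probes.

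By list, acinar genes fell with islet size (median -4.19, camera adjusted p = 9.46e-50; 18 of 32 fell over all genes and 31 adjusted over the list alone; adjusted p = 0.488 with an estimated correlation), with a median of -2.43 on the IgG arrays and -5.96 on the B29 arrays. The Reg family fell with a fitted median of -2.52, or -2.15 with undetected values at the floor (adjusted p = 4.06e-09; adjusted p = 0.488 with an estimated correlation; 1 of 5 fell over all genes, 5 adjusted over the list alone) and the immediate early list with a median of -0.35 (adjusted p = 0.0142; adjusted p = 0.549 with an estimated correlation). For the immediate early list the median was -0.35 on the IgG arrays and 0.04 on the B29 arrays, so that both antibodies did not share the fall. The beta cell identity list rose (median 0.19, adjusted p = 0.00142), as did those of fibroblast and matrix genes (0.28, adjusted p = 0.00163) and oxidative phosphorylation (0.13, adjusted p = 0.0145). With an estimated correlation these 3 were lost: adjusted p = 0.488 with an estimated correlation for the first 2 and adjusted p = 0.549 for the last. The lists of delta and PP cells (0.57, adjusted p = 0.00805) and ribosomal proteins (0.18, adjusted p = 0.00557) rose with quantile normalization, but their medians were -0.03 and -0.06 with median centring. With cyclic loess the median was 0.03 for the delta and PP cell list (camera, adjusted p = 0.409) and -0.00233 for the ribosomal genes. These calls were lost too, with an adjusted p = 0.549 with an estimated correlation for the delta and PP cell list and an adjusted p = 0.488 for the ribosomal list. The 18 other lists did not pass (adjusted p from 0.0874 to 0.828).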

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

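The tests in this part were chosen after the results they address were seen; for the lymphoid genes the list was chosen then but the bound was set before the values of its genes were seen.

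The ratios of B29 to IgG differed in sign between islet sizes and by at least 2-fold for the acinar list and for Reg1, which is why they stand here; the difference between sizes was not tested. The acinar list had a median log2 ratio of 0.29 under 100 µm, 0.48 at 100 to 200 µm and -3.04 over 200 µm. The Reg list stands here on its fitted medians alone (2.05, 0.79 and -0.0109): at 100 to 200 µm 4 of its genes were undetected with IgG, and with these at the floor the median was 0.46, while over 200 µm the same genes lay below background on both arrays, so that no sign was measured there for them or for the list. Reg1, which acinar cells express, stood at 0.61, 1.30 and -4.00.

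Reg2, Reg3a and Reg3b were brighter with B29 in the smallest islets, with a median ratio of 2.44. More acinar RNA on the B29 array was set against this with 10 other dim genes at least 4-fold brighter in small than in large islets. Their median ratio was 0.93 and their highest 1.21 (SD 0.43), so that acinar RNA may account for a part of the difference. The 3 Reg genes lay beyond the highest of those genes by more than their SD. However, they were picked as the 3 highest ratios of this class, so this cannot decide whether acinar RNA is the whole cause. Reg3d, at 1.04, lay within the range of the 10 genes and may follow it. Quantile normalization as the cause was argued against, since the median of the 3 Reg genes stayed at 2.35 with median centring. A difference between the RNA pools that the antibody did not make cannot be told apart from an effect of B29, because there was 1 array per treatment and class. An effect of the antibody on these genes in small islets stays open as a hypothesis.

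On the B29 array of 100 to 200 µm, 53 probes had a detection p under 0.01 and on each other array a detection p of 0.05 or more, against 0 to 10 probes for the other 5 arrays; with a detection p under 0.05 for both, the array did not stand apart (467 against 195 to 555). Among the 31 named genes of the 53 probes are Cxcl13 (8.0 against a mean of 4.18 elsewhere), Igh-6 (7.55 against 4.28), Fcmr (6.56), Igl-V1, Cd79b (5.40) and Cd22. More macrophages as the whole cause was argued against by 9 core macrophage genes: 8 were higher (percentile 99.2), so that a small rise stays open, but their median ratio was 0.21 (SE 0.0508) and their highest 0.48, far below Lyz1 at 1.82. B cells are a candidate source, as a hypothesis from values already seen: all 5 other genes of the B cell list with a probe, detected or not, had a median ratio of 0.54 (SE 0.529, 4 higher, percentile 100), from Igh-6 at 2.84 to Ms4a1 at 0.07 and a probe of Cd22 at -0.05. The 8 T cell genes with a probe had a median of -0.02 (percentile 26.3). In either list 0 genes lay above the floor on both arrays, so the T cell median does not show that T cells were absent. Wider lymphoid tissue cannot be told apart from B cells alone: the median of 17 detected lymphoid genes was 0.54, but 10 of them were detected on this array alone, which fixes the direction, and that of all 27 with a probe was 0.0738 (SE 0.184, 20 higher, percentile 99.99), with 1 gene above the floor on both arrays; an effect of B29 stays open with 1 array.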

How the results depend on the processing

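The alternatives that left out probes bright in small islets or that used 1 treatment alone were chosen after the data were seen; the others were planned. The count of 1 probe for treatment over sizes became 0 with cyclic loess, without background correction, with the second background method, without a filter, with 1 probe per gene and without the size factor, and ran from 0 to 3 with arrays or pairs left out (3 without the pair over 200 µm); leaving out either array of a pair leaves the other fitted exactly, which equals leaving out the pair. In each class the counts grew with a 1.5-fold rule (1014, 579 and 979 from the smallest class to the largest) and shrank without background correction (12, 19 and 51) or with the second background method (21, 25 and 67), since both shrink differences of dim probes. Over 200 µm the count was 93 without the probes bright in small IgG islets, and median centring gave 8 brighter and 158 dimmer in place of 31 and 114 (4.8% against 21.4% brighter). Probes 1.5-fold apart in the same direction numbered 2 with 1 probe per gene, 1 with a 2-fold rule and 3 without background correction, and 34 to 68 where fewer classes had to share a direction.

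For over 200 against under 100 µm, the count was 49 with 1 probe per gene, 57 for probes detected on all 6 arrays, 0 without background correction, with the second background method or without a filter, and 0 to 224 with an array left out (0 without the B29 array under 100 µm, 5 without the IgG array under 100 µm and 224 without the IgG array over 200 µm); at 2-fold and without a test, the IgG arrays alone gave 171 and the B29 arrays 264. For 100 to 200 against under 100 µm it was 1 for probes detected on all 6 arrays, 46 with a stricter detection p, 61 with a trended and robust fit, 31 without the treatment factor, 0 without background correction, with the second background method or without a filter, and 0 to 142 with an array left out (at most 1 without any array of the 2 classes compared, 142 without either array over 200 µm). For over 200 against 100 to 200 µm it ran from 0 to 61, the highest without the IgG array over 200 µm. A lone array was assumed to vary like the others.

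For lists, 0 treatment and 0 size lists passed with an estimated correlation and 0 and 0 with fry; 10 treatment lists passed with median centring, 6 with cyclic loess or the second background method, 3 without background correction and 2 to 8 with a pair left out, and 6 size lists passed with either other scaling and 7 without background correction. Among lists that passed, the direction turned for the size medians of delta and PP cell genes with median centring (-0.0287) and of ribosomal genes with cyclic loess (-0.00233) and median centring (-0.0571). Among those that did not pass, the size medians of alpha cell and heat shock genes turned with both scalings (alpha cell 0.10 to -0.06 and -0.11, heat shock 0.17 to -0.11 and -0.09). With a pair left out, the treatment median of the acinar list ran from -1.36 to 0.332 and that of the macrophage list from -0.0511 to 0.294. Except where the construction of an alternative is named, the cause was not tested. Medians of all genes moved by less than 0.1 under each scaling. Most probes lay near background, which limits ratios of dim genes to bounds.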

Other observations

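The tests of regrouped arrays and of handling in this part were chosen after the results were seen; those of STAT5 targets and of endocrine progenitor genes were set after Cish and Neurog3 had been noticed but before the values of their lists were seen, except that the look at members above the floor came after.

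Lists of stress and blood genes not described above had their lowest ratios in the smallest islets. There, 4 of 15 genes of endoplasmic reticulum stress were higher with B29 (median -0.24), with Ddit3 at -1.18 and Atf4 at -0.95, against medians of 0.05 and -0.08 in the larger classes (camera, adjusted p = 0.135). The red blood cell list of 4 genes had medians of -0.65, 0.34 and -0.28, with Hba-a1 at -0.77 and Hbb-b2 at -0.86 in the smallest class (adjusted p = 0.383). Inflammation genes had medians of -0.22, 0.07 and -0.05 (adjusted p = 0.559), with Tnfaip3 at -0.84 and Nfkbia at -0.65 under 100 µm. None of these lists passed over the 3 classes, but the first passed with median centring (adjusted p = 0.0395) and without the pair of 100 to 200 µm (adjusted p = 0.0311), and the red blood cell list without that pair (adjusted p = 0.0174). Over all 3 pairs both had an adjusted p = 0.732 with an estimated correlation.

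Lists that showed no shift over the classes were interferon response (median ratios -0.06, 0.01 and 0.03, adjusted p = 0.871), class I antigen presentation (0.08, 0.09 and 0.07, adjusted p = 0.283), endothelial (-0.08, 0.11 and -0.14, adjusted p = 0.559), ductal (0.01, -0.05 and -0.13, adjusted p = 0.850), ribosomal protein (0.06, 0.05 and -0.05, adjusted p = 0.864), oxidative phosphorylation (-0.01, 0.07 and -0.06, adjusted p = 0.969) and sex-linked genes (-0.17, 0.16 and -0.19, adjusted p = 0.974). The endothelial gene Vwf stood at 1.18 in the class of 100 to 200 µm.

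For Cish, dimmer with B29 in all 3 classes, of the 10 splits of the 6 arrays into 3 and 3, 5 gave at least 1 probe, the real split with 1 and the highest other with 39. So few splits cannot give a share under 0.05. Each other split with a probe kept the 2 arrays of a class together for 2 classes, so that it tests the remaining class alone. Those with 39 test the difference between the 2 arrays over 200 µm, a structure of the samples. The other splits that, like the real one, put 1 array of each class in each group gave 0. Handling that lowered stress genes was set against this with 18 immediate early and heat shock genes. Their median was -0.48 under 100 µm and -0.000969 over 200 µm (SE 0.0688, 9 lower), where a median of -0.45 would match the ratio of Cish. As a set, the 18 genes thus did not follow Cish over 200 µm. However, Npas4 (-0.84), Errfi1 (-1.06) and the immediate early gene Csrnp1 (-0.92), outside the 18, were dimmer there too. They were named for their low ratios, so handling as the cause stays open. The reading assumes that handling moves Cish and the 18 genes in a fixed proportion. Its SE treats the genes as independent, though the estimated correlation was 0.32 in the immediate early and 0.30 in the heat shock list. Lower STAT5 signalling, a hypothesis for Cish, stays open: 10 other STAT5 targets had a median of -0.0672 (SE 0.0517), which the bound set beforehand would have read as against it, but 6 of them lay at or below the floor on at least 1 array, and the 4 others (Ccnd2, Igfals, Socs2 and Lifr) had a median over classes of -0.23 (SE 0.0568). Over 200 µm 1 of these 4 was lower (median 0.05, SE 0.159), where Cish stood at -1.35, but under 100 µm their median of -0.48 (SE 0.251) lay within 2 SE of 0, so that the reading used for handling decides nothing. A difference between the pools of mice stays open too.

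Neurog3 was brighter with B29 in all 3 classes without passing the test, and a wider endocrine progenitor programme was set as a hypothesis. The median of 14 other progenitor genes was -0.0166 (SE 0.0232), and that of the 11 above the floor on all 6 arrays was -0.03 (SE 0.0250), which argues against a shift of the whole list; islet cells express several of them, so a small share of progenitor cells stays open.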
